A study of Mus musculus with 35 samples.

How the data were processed

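The series holds 35 mouse chromatin immunoprecipitation libraries from stromal-adherent pre-B cell progenitors, wild type (WT) or with a dominant-negative Ikaros allele driven by CD2-Cre (IKDN), at passages 3 to 8. A peak list was available for 33 of them, 16 WT and 17 IKDN. The 2 input libraries had none. 15 targets were mapped in both genotypes: the histone marks H3K27ac, H3K4me1, H3K4me2, H3K4me3, H3K36me3 and H3K27me3, RNA polymerase II phosphorylated on serine 5 (RNAPII), the Mediator subunit MED1, and the transcription factors E2A, EBF1, PAX5, IRF4, ETS1, TEAD1 and Aiolos. Ikaros was mapped in WT cells only, LHX2 and LMO2 in IKDN cells only. Each genotype and target has 1 library, so there are no replicates, no standard deviations and no p-values, and a difference between genotypes cannot be set against the spread between cultures.

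Each list gives, per the file headers, the coordinates of a peak, a peak score, and the distance from the peak centre to the nearest annotated transcription start site (TSS). The submitters' processing notes name bcl2fastq 1.8.3, BWA, STAR and HOMER, and both the mm10 and the mm9 build. The positions match mm10: of the transcription start sites worked out from the deposited distances, 98.8% lay within 1000 bp of their gene in the GRCm38 annotation. The unit of the peak value is a score as the authors deposited it, and its scale is not stated. Within a list the scores are whole multiples of a smallest step (for all scores up to 10 in 32 lists, for 96.4% in the WT TEAD1 list), as a tag count multiplied by a constant would be. If that constant scales to 10 M tags (M, mega), which is an inference, the IKDN H3K4me3 library with 10.7 M tags is the smallest and the IKDN H3K27me3 library with 37.5 M tags the largest. Scores were used to rank, filter and sum peaks within a list. Only the alternative that calls genes by summed score compared scores between the WT and IKDN lists, which takes their scales to be equal.

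Peaks on the 19 autosomes, X and Y were used. 3 lists are incomplete: the WT E2A list stops at 157 Mb of chromosome 2 and has no peaks on chromosomes 3 to 9 and X, the WT ETS1 list has none on chromosome 2, and the IKDN PAX5 list stops at 32.6 Mb of chromosome 9 and has none on X. A list counted as incomplete on a chromosome if its last peak lay more than 10 Mb before the last peak of all lists. For the occupancy of distal regions, each list was used on the chromosomes complete in that list. Every other comparison used only chromosomes that were complete in all its lists. That choice was made after seeing the data, as were the alternatives restricted to autosomes, keeping incomplete chromosomes, using equal peak numbers for super-enhancers, and restricting the exchange of marks to genes with both. The tests of explanations for the longer IKDN lists, for stromal cells in the WT cultures and for the segment copies were also chosen after seeing the data. The other comparisons between genotypes, the gene lists, the remaining alternatives and the rule for named genes were fixed before the data were examined.

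Peaks of both genotypes counted as shared if they overlapped by at least 1 bp. Shares carry exact 95% Clopper-Pearson intervals, which hold counting error only. Chance overlap came from 100 circular shifts of the peaks along each chromosome. Distal H3K27ac regions were peaks of both genotypes merged, with no TSS within 2.5 kb, classed as WT-only, shared or IKDN-only. Super-enhancers were distal H3K27ac peaks stitched at 12.5 kb, ranked by summed score, above the point where the scaled rank curve has slope 1. For each of 21887 protein-coding RefSeq genes the length covered by peaks was taken over the gene body and 10 kb on each side. A gene was called higher in IKDN with at least 1000 bp more and at least 1.5 times the covered length of WT, and lower in the reverse case. These calls are thresholds, not tests. 15 gene lists were set as percentiles among 10000 random lists of equal size, matched in 20 bins of mean covered length. Observed pairs of calls were set beside the number that independent calls would give. The similarity of 2 lists is the Jaccard index of their 5000 top-ranked peaks.

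Named genes are those coding for the immunoprecipitated factors; per list, up to 3 genes with the largest gain and 3 with the largest loss of H3K27ac among those called; the genes nearest to the 10 top-ranked super-enhancers of each genotype alone; the 5 genes with the largest loss and gain of H3K27me3 among those with an opposite H3K27ac call; and the genes nearest to the 5 top-ranked LHX2, LMO2 and TEAD1 peaks in IKDN-only distal regions. Any other named gene is said to be chosen after its values were seen.

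Alternatives were the overlap rule (50% of both peaks, or within 1000 bp), the top-scored 50% of the lists, equal peak numbers, a 1 kb distance from a TSS, H3K4me1 or MED1 in place of H3K27ac, stitching at 5 kb, ranking by covered length, promoter peaks kept, a 50 kb flank, and peak numbers (at least 2 more and 1.5 times) or summed scores in place of covered length. An alternative value counted as the same if it stayed within 1.5 times the reported one, or for an occupancy ratio within its 95% counting interval, and as reversed if the direction turned. The gene calls were tested on simulated data, a copy of the WT H3K27ac list with planted changes: 34 of 34 genes with 2 times the covered length were recovered, 32 of 33 at 0.333 times, 0 of 34 at 1.25 times, and 0 of 21354 genes away from the planted ones were called. Away from the planted genes the copy equalled the original, so that last count and the one at 1.25 times were fixed by construction. The simulation checks the computation and holds no spread between libraries. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 with random seed 20.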

Results

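H3K27ac, a mark of active enhancers and promoters, covered more of the integrin and focal adhesion genes in IKDN than in WT pre-B cells. Of 30 genes on that list, 17 were called higher and 2 lower, where random lists of matched coverage gave on average 5.65 higher and 3.79 lower. The largest gain was at Itga9, an integrin alpha chain, with 43.2 kb covered in WT and 101 kb in IKDN cells. Tns3, a tensin that links integrins to actin, had 29.6 and 82.2 kb, and Lasp1, an actin-binding protein of focal adhesions, had 9.62 and 32.2 kb. The exceptions were Tln2, a talin, with 10.7 kb in WT and 2.99 kb in IKDN, and Cav1, which codes for caveolin 1, with 1.44 kb and 0. The median difference over the list was 3101 bp, above all 10000 random lists. Separate libraries gave the same direction for this list: H3K4me1 was called higher at 17 genes and lower at 1, H3K36me3, a mark of transcribed gene bodies, at 15 and 0, and RNAPII at 10 and 4. Matched random lists gave on average 4.89 and 4.79 for H3K4me1, 5.22 and 0.635 for H3K36me3, and 5.60 and 6.53 for RNAPII. At Tns3 the H3K36me3 coverage was 25.8 kb in WT and 140 kb in IKDN, and at Itga9 it was 0 and 67.6 kb.

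Other gene groups were set beside random lists in the same way. Of 25 cytoskeleton and small GTPase genes, 9 were called higher for H3K27ac and 2 lower (percentile of the median 99.4). Among them Dock9, an activator of Cdc42, had 11.8 kb in WT and 35.4 kb in IKDN cells, and Cald1, which codes for the actin-binding caldesmon, 3.27 and 14.9 kb. Myl9, a myosin light chain, had 5.14 kb in WT and 2.03 kb in IKDN, and Diap2, a formin, 3.05 and 1.40 kb. Over this list RNAPII was higher at 5 genes and lower at 8, near the 4.88 and 7.09 of matched random lists. H3K4me1 was higher at 6 and lower at 1 (random 4.22 and 3.96), with a median difference of -121 bp (percentile 51.3). H3K36me3 was higher at 10 and lower at 2 (random 4.52 and 0.543). Of 25 Hippo pathway genes and YAP-TEAD targets, 9 were higher and 2 lower (percentile 95.7). Ptpn14, a phosphatase that binds YAP, had 0.678 kb in WT and 28.1 kb in IKDN, Nuak2 had 5.81 and 18.96 kb, and Crim1 had 13.3 and 21.4 kb. The lower members belong to the kinase core of the pathway: Stk3, which codes for the kinase MST2, had 40.5 and 3.61 kb, and its scaffold Sav1 had 6.80 and 4.06 kb. RNAPII went the other way over the Hippo list, with 6 genes higher and 12 lower (random 6.22 and 5.78), while H3K36me3 was higher at 11 and lower at 0 (random 4.48 and 0.609).

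The growth factor, Wnt, Notch and TGF-beta list had 10 genes higher and 5 lower of 27 for H3K27ac (percentile 94.4). H3K4me1 was higher at 11 and lower at 3 (random 4.59 and 4.06), and H3K4me2 at 7 and 2 (random 2.48 and 2.08). RNAPII was higher at 5 and lower at 6, near the random 4.55 and 4.88. H3K4me3 went the other way, higher at 1 and lower at 6 (random 0.934 and 2.31). Igf1r, the insulin-like growth factor receptor, had 4.19 kb in WT and 41.5 kb in IKDN cells, a ratio of 9.91, and its H3K36me3 coverage was 0.50 and 114 kb. Nrp1, a semaphorin and VEGF co-receptor, had 2.58 and 23.6 kb, and Smad3, a transducer of TGF-beta, 22.1 and 43.8 kb. Smad7, an inhibitor of the same pathway, had 16.3 and 10.2 kb, and the BMP receptor genes Bmpr1a and Bmpr2 had 3.69 and 1.11 kb, and 5.87 and 3.60 kb. Of 30 cell junction and epithelial genes, 8 were higher and 4 lower, where random lists gave 2.93 and 1.91. The median difference was 0, as in typical random lists (percentile 49.7), while genes higher minus lower lay at percentile 91.2. RNAPII was higher at 11 genes of this list and lower at 1 (random 4.51 and 3.42). H3K36me3 was higher at 8 and lower at 1 (random 3.90 and 0.843), and H3K4me1 at 8 and 4 (random 4.04 and 4.35). H3K4me2 was higher at 3 and lower at 4 (random 3.27 and 2.35), and H3K4me3 at 3 and 5 (random 0.832 and 2.01). Ctnnd1, which codes for p120 catenin, had 5.39 kb in WT and 16.0 kb in IKDN, and the polarity genes Pard3 and Pard6g had 0.992 and 13.0 kb, and 5.12 and 14.9 kb. Cttnbp2 had 6.14 kb in WT and 0 in IKDN, Esrp1, an epithelial splicing regulator, 4.71 and 1.04 kb, and Marveld1 2.65 and 1.11 kb.

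Genes of B lineage identity had less H3K27ac in IKDN cells: 7 of 27 were called lower and 2 higher, and the median of the list lay at percentile 0.915 of the random lists. Blk, a Src-family kinase of B cells, had 22.7 kb in WT and none in IKDN cells, its H3K36me3 coverage was 24.6 kb and 0, and its H3K27me3 coverage, the Polycomb mark, was 7.18 and 36.4 kb. Bank1, a scaffold of B cell receptor signalling, had 20.6 and 5.50 kb, and Ebf1, an early B cell transcription factor, 133 and 73.3 kb. The higher members were Cd74, the invariant chain of MHC class II, with 7.43 and 16.6 kb, and Cd72, a B cell surface receptor, with 7.79 and 12.2 kb. Of 25 genes of pre-B differentiation and pre-BCR signalling, 4 were higher and 6 lower (percentile 24.6). Il2ra, which codes for the pre-B surface marker CD25, had 23.1 kb in WT and 9.75 kb in IKDN, and Cd2 had 11.6 and 0.350 kb. Ikzf3, which codes for Aiolos, went the other way with 14.9 and 38.8 kb, as did the Ras activator Rasgrp3 with 7.76 and 27.2 kb and the adaptor Sh2b3 with 9.01 and 17.4 kb. RNAPII did not follow over the IKDN-only super-enhancer at Ikzf3, where it covered 79.8 kb in WT and 15.3 kb in IKDN cells. Counted by number of peaks, the B lineage list turned to 6 more genes higher than lower and the pre-B list to 2 more. That setting moved all protein-coding genes towards higher and had no random lists, so it does not show a turn relative to other genes.

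Of 25 cell cycle genes, 1 was called higher for H3K27ac and 4 lower (percentile 9.05). Ccnd3, the D-type cyclin that pre-B cells depend on, had 70.2 kb in WT and 30.3 kb in IKDN cells, while Ccnd1 had 2.27 and 5.98 kb. Cdkn1a, which codes for the cell cycle inhibitor p21, had 7.35 and 3.69 kb, and Mycn 5.25 and 1.36 kb. The 30 extra-lineage and progenitor transcription factors had 5 higher and 7 lower members (median difference -36 bp, percentile 1.73). The number of peaks, which moved all genes towards higher, turned that balance to 2 more higher. Over this list H3K4me1 was higher at 8 genes and lower at 5, H3K4me2 at 6 and 2, H3K36me3 at 9 and 2, and H3K4me3 at 3 and 12. Matched random lists gave on average 4.26 and 0.896 for H3K36me3 and 0.897 and 2.21 for H3K4me3; over all protein-coding genes H3K36me3 was higher at 3231 and lower at 524, and H3K4me3 at 476 and 1220. Hlf, a factor of haematopoietic stem cells, had 0 in WT and 21.7 kb in IKDN, Rbpms had 8.65 and 31.5 kb, and Lmo2 2.65 and 7.98 kb. Gfi1b, which codes for a transcriptional repressor, had 19.8 and 5.50 kb, Nfe2 had 11.4 and 6.80 kb, and Runx2 7.70 and 4.26 kb.

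**Figure D1:**
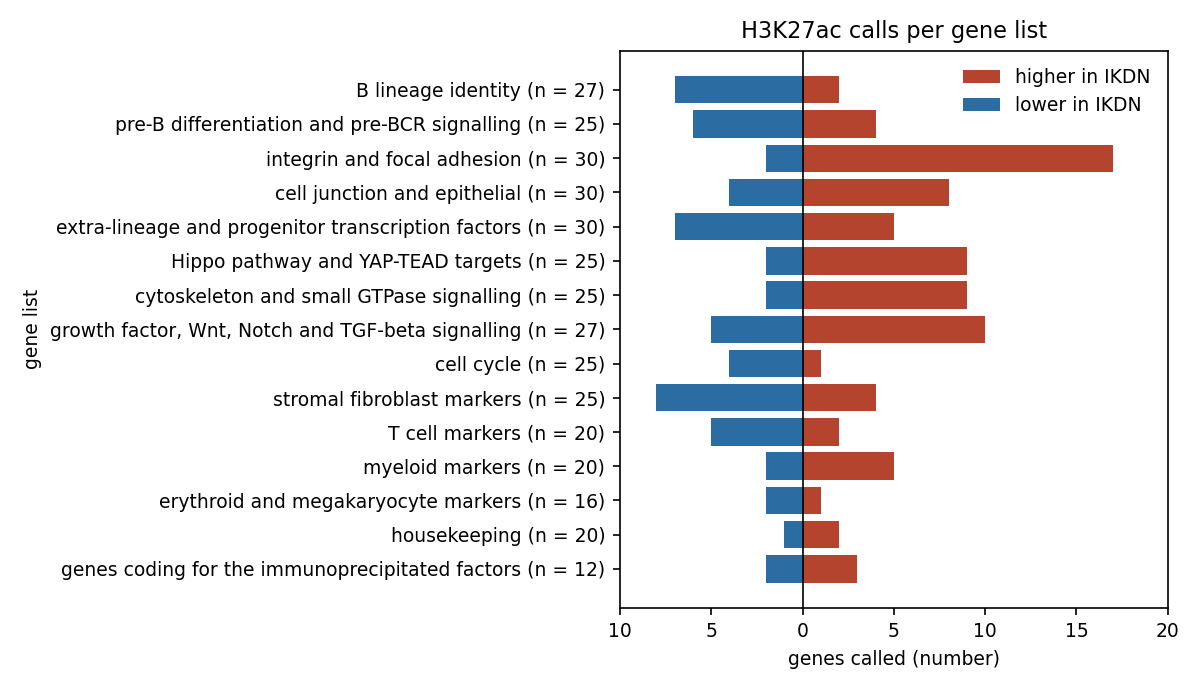
Number of genes per fixed list called higher (right) or lower (left) in IKDN than in WT for H3K27ac covered length, with the number of genes on each list in brackets. The integrin and focal adhesion list has 17 genes to the right and 2 to the left, the B lineage list 2 and 7.

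Markers of other cell types and housekeeping genes were set beside random lists as well. The percentile of the median for H3K27ac was 45.3 for stromal, 2.16 for T cell, 46.3 for myeloid, 43.4 for erythroid and megakaryocyte markers, and 32.3 for housekeeping genes. For the stromal, myeloid and erythroid lists the median difference was 0, as was the typical median of their random lists, so these percentiles rest on ties. Percentiles of the net call, genes higher minus genes lower, were 1.60, 4.26, 89.0, 19.8 and 49.5 in the same order. Of 25 stromal fibroblast markers, 4 were higher for H3K27ac and 8 lower (percentile of the net call 1.60); Mmp2 had 7.69 kb in WT and none in IKDN, Prrx1 5.95 and 2.04 kb, and Col1a1 3.22 and 1.15 kb, while Fn1 had 1.0 and 5.31 kb, Acta2 3.57 and 8.08 kb, and Sparc 0.50 and 3.24 kb. For H3K4me3, the promoter mark, the same markers were higher at 1 gene and lower at 15. For this list, the extra-lineage one and the growth factor one, the IKDN H3K4me3 library was also the smaller, with 10.7 M tags against 29.6 M in WT on the inferred scale. Of 20 T cell markers, 2 were higher (Cd247 with 4.34 and 20.2 kb, Cd4 with 2.38 and 4.93 kb) and 5 lower, among them Lat with 11.1 and 4.27 kb and Lck with 12.52 and 6.29 kb. Of 20 myeloid markers, 5 were higher, led by Csf1r with 0.50 and 4.41 kb, Cebpa with 0 and 3.63 kb, and Csf2ra with 2.22 and 5.03 kb, and 2 were lower, the lysozyme genes Lyz1 with 4.77 and 1.05 kb and Lyz2 with 2.09 and 1.05 kb; with a 50 kb flank 2 more were lower than higher, and by number of peaks the balance was 0. Of 16 erythroid and megakaryocyte markers, 1 was higher (Pf4, 0 and 1.67 kb) and 2 lower (Gfi1b, and Tal1 with 1.87 kb and 0). Of 20 housekeeping genes, 2 were higher (Gapdh, 3.35 and 5.21 kb, and Gusb, 2.45 and 5.50 kb) and 1 lower (Ywhaz, 15.6 and 8.70 kb).

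Over all 21887 protein-coding genes H3K27ac was called higher at 2709 and lower at 1859. Calling genes by summed score in place of covered length turned this balance, to 0.647 genes higher per gene lower. Among the lists it turned only those of housekeeping genes and of the genes coding for the mapped factors. The integrin list had 16 more genes higher than lower and the B lineage list 18 more lower than higher. The Hippo list fell from 7 more higher to 1 and the growth factor list from 5 to 1. The median H3K27ac score was 38.8 in the WT and 28.2 in the IKDN list. As the setting moved all genes towards lower and had no random lists, these balances do not show how a list moved relative to other genes.

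The genes coding for the mapped factors themselves had 3 higher and 2 lower members of 12 for H3K27ac. Ikzf1, the gene of Ikaros, had 24.0 kb in WT and 47.4 kb in IKDN cells, Ikzf3 and Lmo2 were also higher, and Ebf1 and Tcf3, which codes for E2A (20.7 and 11.8 kb), were lower. Pax5 differed by less than the threshold (29.9 and 30.6 kb), as did Lhx2 (7.155 and 9.54 kb), Tead1 (18.8 and 27.03 kb), Ets1 (54.8 and 62.3 kb), Irf4 (18.0 and 13.7 kb), Med1 (6.84 and 7.95 kb) and Polr2a (5.30 and 5.51 kb). H3K27me3 was lower at 5 of the 12 and higher at 0 (percentile of the median 0.80). Its coverage at Lmo2, a bridging factor of haematopoietic progenitors, was 30.1 kb in WT and 0 in IKDN, at Lhx2, a LIM homeodomain factor, 29.3 and 1.2 kb, and at Tead1, the DNA-binding partner of YAP, 13.6 and 1.79 kb. H3K36me3 coverage was 3.79 and 11.8 kb at Lmo2, 14.7 and 29.1 kb at Lhx2, and 0 and 29.6 kb at Tead1. RNAPII coverage was 1.79 and 14.2 kb at Lmo2 and 2.47 and 16.3 kb at Lhx2, but 40.4 and 19.1 kb at Tead1.

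The loss of H3K27me3 and the gain of H3K27ac fell on the same genes more often than independent calls would give. H3K27me3 was lower in IKDN cells with H3K27ac higher at 1089 genes, against 558 for independent calls, a ratio of 1.95. The opposite exchange was seen at 431 genes against 278, a ratio of 1.55, whereas both marks were lower at 263 genes against 383 and both higher at 321 against 406. Arhgap26, a GTPase-activating protein that binds focal adhesion kinase, had the largest loss of H3K27me3 in this group, from 105 kb in WT to 0.629 kb in IKDN, with 40.4 and 99.0 kb of H3K27ac. Next came Pak3, a Rac and Cdc42 effector kinase (93.6 and 10.1 kb of H3K27me3), Lgr6, an R-spondin receptor (79.6 and 2.60 kb), Rbfox2, a splicing regulator (68.5 and 1.38 kb), and Lhfp (63.8 kb and 0). H3K36me3 coverage at Lhfp was 0 in WT and 80.6 kb in IKDN, and at Rbfox2 0 and 27.9 kb. Among the genes with more H3K27me3 and less H3K27ac, Megf10, an engulfment receptor, had 3.33 and 126 kb of H3K27me3 and 33.4 kb and 0 of H3K27ac. The others were Pde11a, a phosphodiesterase (1.11 and 105 kb of H3K27me3), Sytl2, a Rab27 effector (0 and 94.1 kb), Crb1, a polarity protein (12.4 and 103 kb), and Dlg5 (5.21 and 94.3 kb). Within 2.5 kb of transcription start sites the ratios were larger, 4.10 and 2.38, while among genes with a peak of both marks in either genotype they were 1.37 and 2.03, so that their order turned.

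Away from promoters, factor peaks lay more often at regions acetylated in the genotype their library came from. The distal H3K27ac regions comprised 9661 WT-only, 11304 shared and 14252 IKDN-only regions. A WT Ikaros peak lay in 31.6% (95% interval 30.7 to 32.5) of the WT-only, 69.2% of the shared and 11.3% (10.8 to 11.8) of the IKDN-only regions, where shifted peaks gave 2.03, 4.91 and 1.95%. Aiolos in WT cells had few peaks, in 1.04, 7.63 and 0.498% of the classes, and in IKDN cells in 0.414, 4.68 and 1.85%. LHX2 in IKDN cells lay in 9.07% of WT-only, 51.6% of shared and 18.5% (17.8 to 19.1) of IKDN-only regions, and LMO2 in 6.15, 43.5 and 13.8% (13.2 to 14.4). TEAD1 in IKDN cells lay in 11.9, 58.7 and 27.03%, and in WT cells in 9.74, 30.0 and 6.36%. EBF1 lay in 12.6, 34.1 and 7.65% of the classes in WT cells and in 8.91, 39.2 and 18.4% in IKDN cells. WT MED1 lay in 4.52, 19.05 and 0.653%, the last below the 0.906% of shifted peaks, and IKDN MED1 in 4.90, 52.3 and 15.1%. The share of IKDN-only over that of WT-only regions was 0.223 in WT and 2.69 in IKDN cells for E2A, 0.260 and 2.24 for IRF4, 0.274 and 2.66 for ETS1, and 0.442 and 1.62 for PAX5, beside 0.357 for Ikaros, 2.04 for LHX2 and 2.24 for LMO2. The regions differ between the genotypes for the incomplete lists, with 11 chromosomes in WT and 21 in IKDN for E2A. For ETS1 they were 20 and 21, and for PAX5 21 and 18. Ikaros, LHX2 and LMO2 were mapped in 1 genotype each, so their placing cannot be separated from the genotype of the library. With regions defined by MED1 in place of H3K27ac, Ikaros lay more often in the IKDN-only than in the WT-only class, by a ratio of 2.35 where H3K27ac gave 0.357, and the WT lists of EBF1 (0.606 to 2.38) and Aiolos (0.481 to 1.06) turned as well. The MED1 classes are unlike in acetylation, though. Of all WT-only MED1 peaks, promoters included, 62.1% lay outside H3K27ac and 12.4% in WT-only H3K27ac. Of the IKDN-only MED1 peaks 18.7% lay outside H3K27ac. The turn therefore does not show Ikaros at gained rather than lost acetylated regions. With equal numbers of H3K27ac peaks the excess of IKDN-only over WT-only regions disappeared (ratio 0.991), as that setting nearly forces.

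**Figure D2:**
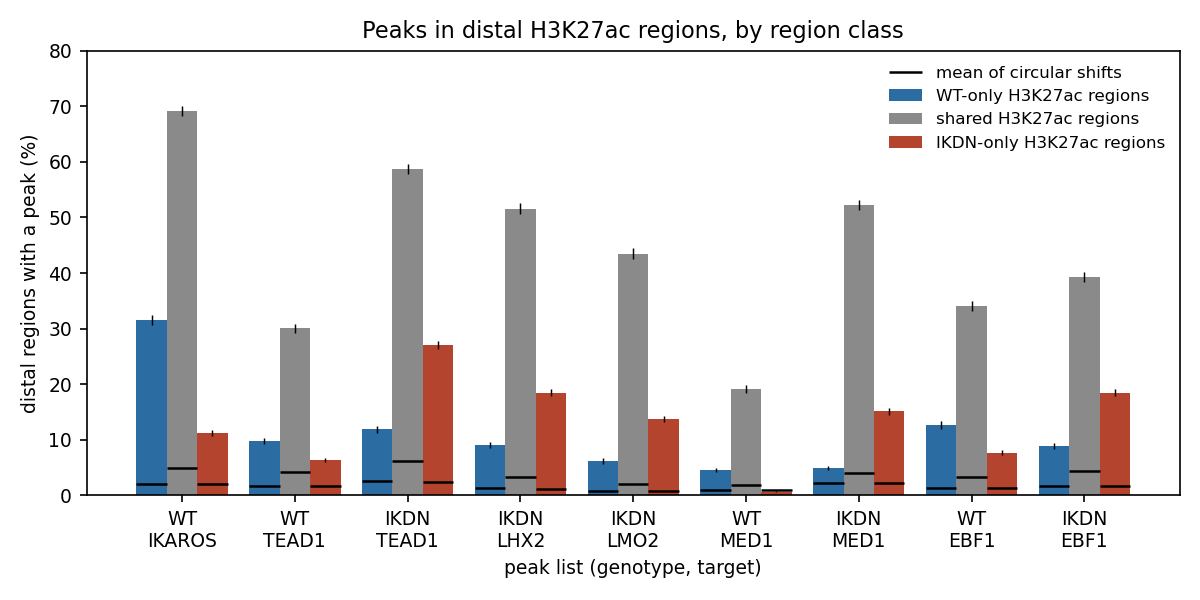
Share of distal H3K27ac regions (%) with a peak of each list, for WT-only, shared and IKDN-only regions; error bars are 95% Clopper-Pearson intervals (counting error only) and black lines the mean of the circular shifts. Ikaros in WT cells is at 31.6, 69.2 and 11.3% and LHX2 in IKDN cells at 9.07, 51.6 and 18.5%.

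LHX2, LMO2 and TEAD1 peaks overlapped each other and those of the other factors in IKDN cells. An LMO2 peak overlapped 28.4% of 26634 LHX2 peaks and a TEAD1 peak 35.2%, where shifted peaks gave 0.258 and 0.859%, while PAX5 overlapped 49.4%, IRF4 35.3% and ETS1 32.3%. Of 15437 LMO2 peaks, 49.0% overlapped LHX2 and 47.0% TEAD1, beside 68.4% for PAX5, 55.7% for ETS1, 52.8% for E2A and 50.7% for IRF4. Of 47735 TEAD1 peaks, 19.6% overlapped LHX2 and 15.2% LMO2, beside 38.9% for PAX5, 27.7% for ETS1 and 25.2% for IRF4. The shares with PAX5 are of peaks on the 18 chromosomes complete in its list. All 3 of LHX2, LMO2 and TEAD1 had a peak in 1056 IKDN-only regions (7.41%, interval 6.98 to 7.85, against 0.688% for independent placing), in 3368 shared regions (29.8% against 13.2%) and in 166 WT-only regions (1.72% against 0.0662%). Independent placing here takes no account of region width. The median width of IKDN-only regions was 500 bp with none of the 3 factors and 2308.5 bp with all 3. Wide regions can hold peaks of every factor, so the excess alone does not show joint placing. Most LHX2 peaks lay elsewhere than at gained acetylation: 49.4% in regions acetylated in both genotypes, 34.4% outside H3K27ac and 12.49% in IKDN-only regions. The top-ranked LHX2 peaks in IKDN-only distal regions lay nearest to Odf1 (42.6 kb from its start site), Caprin1 (74.3 kb), Alpk2 (163 kb), Myo6, an actin-based motor (76.8 kb), and Trio (55.3 kb). Those of LMO2 lay nearest to Spry4, an inhibitor of receptor tyrosine kinase signalling whose H3K27ac coverage was 0 in WT and 21.3 kb in IKDN, and to Bnc1, Rpl37a, Saraf and Mrgpra2a. Those of TEAD1 lay nearest to Dgkd, a diacylglycerol kinase, Slc3a2, which codes for the integrin-associated amino acid transporter subunit CD98, Tas2r134, Ice1 and Pitpnm3. The nearest start site is a label of place and need not be the gene that a region acts on.

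Super-enhancers, clusters of H3K27ac with the highest summed score, numbered 600 in WT and 882 in IKDN cells. Of the WT ones 371 (61.8%, interval 57.8 to 65.7) overlapped an IKDN super-enhancer and 229 did not. Of the IKDN ones 378 (42.9%, 39.6 to 46.2) overlapped and 504 did not. Lengths in the genotype that holds a super-enhancer count its distal peaks, those in the other genotype all H3K27ac peaks. The paired lengths are therefore unlike where start sites lie inside the region, as at Slco4a1 and Arhgap23. The second-ranked of the IKDN-only group lay in Trio, which codes for an exchange factor of Rac1: 70.7 kb of it was acetylated in IKDN and 2.58 kb in WT cells, with 18 LHX2, 14 LMO2 and 12 TEAD1 peaks. Over the whole of Trio, H3K36me3 covered 0.50 kb in WT and 186 kb in IKDN, and H3K27me3 18.5 kb and 0. The first-ranked lay at Hjurp, the chaperone of the centromeric histone CENP-A (15.2 kb in IKDN, 16.3 kb with all IKDN peaks, and 3.67 kb in WT). There the IKDN lists of Aiolos, EBF1, E2A and PAX5 also had peaks of rank 1, 5, 12 and 17. Further ones lay nearest to Xxylt1 (63.0 and 38.8 kb), Mgll, which codes for monoacylglycerol lipase (39.0 and 10.6 kb), Slco4a1 (23.6 and 28.9 kb), Arhgap23, a GTPase-activating protein (37.2 and 12.9 kb), Ccr1, a chemokine receptor (21.01 and 5.0 kb), Itpkb, an inositol trisphosphate kinase (38.3 and 21.4 kb), Ikzf3 (30.2 and 10.2 kb) and Ppp2ca, a catalytic subunit of protein phosphatase 2A (19.2 and 14.2 kb). At the one near Ikzf3 RNAPII went against H3K27ac, with 15.3 kb in IKDN and 79.8 kb in WT.

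The WT-only super-enhancers included a 115.9 kb region of the immunoglobulin kappa locus, with 68.3 kb of H3K27ac in WT and 8.41 kb in IKDN cells. It overlapped 16 annotated genes or segments, among them the V segments nearest the J cluster and J segments. Its nearest other gene is Rpia. Lengths in WT count distal peaks here, and those in IKDN all H3K27ac peaks. The first-ranked lay near Herpud1 (37.4 kb in WT and 10.4 kb in IKDN). Others lay near Cxcr4, the receptor of CXCL12 that holds B cell progenitors in the marrow (51.7 and 13.6 kb), Rere (47.5 and 16.3 kb), B3gnt2 (47.4 and 18.4 kb), Cux1, a homeobox gene (49.0 and 9.03 kb, while the gene and its flanks had 22.2 and 34.4 kb), and Fgd2, a Cdc42 exchange factor of B cells and other antigen-presenting cells (36.5 and 15.4 kb). 3 lay on copies of a Trav13, Trav14 and Trav15 segment cluster in the T cell receptor alpha locus, with 20.7, 20.3 and 19.98 kb in WT and 0.768, 1.40 and 1.40 kb in IKDN; their nearest start sites, far outside the segments, were those of Dad1 and Olfr1507. MED1 from WT cells was present in 37.1% of the 504 IKDN-only super-enhancers and MED1 from IKDN cells in 99.6%; in the 229 WT-only ones it was 87.3 and 86.9%. TEAD1 was present in 71.4% of the IKDN-only ones with WT and in 100% with IKDN peaks, and in 87.3 and 94.3% of the WT-only ones. LHX2 was present in 97.2 and 94.8%. Most were not a matter of presence or absence, since 456 of the 504 had some H3K27ac peak in WT and 216 of the 229 had one in IKDN. Without any such peak the ratio of IKDN-only to WT-only was 3.69, and ranked by covered length it was 1.33, where the summed score gave 2.20.

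**Figure D3:**
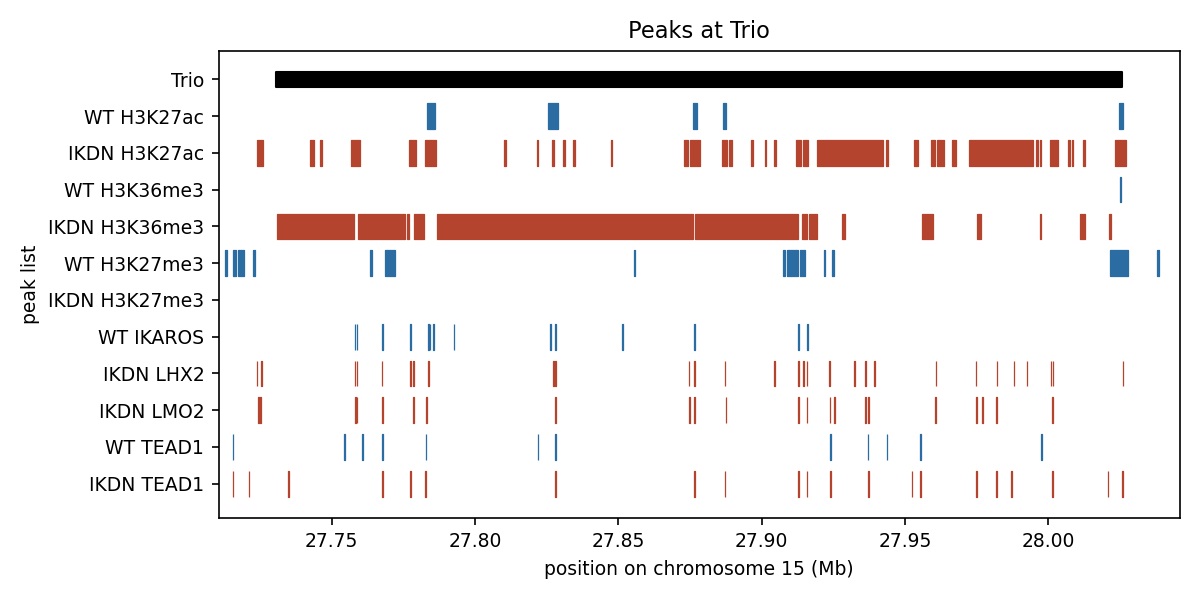
Peaks of WT (blue) and IKDN (red) lists along Trio on chromosome 15, from 27.7 to 28.0 Mb, with the gene body in black and position in Mb on the horizontal axis. H3K27ac and H3K36me3 cover 90.9 and 186 kb of the gene and its 10 kb flanks in IKDN cells, against 10.3 and 0.50 kb in WT.

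The share of peaks found in both genotypes varied between targets and with the genotype it was counted in. Of WT H3K4me3 peaks 81.8% (interval 81.2 to 82.3) overlapped an IKDN peak, of H3K4me2 peaks 75.7%, of H3K4me1 peaks 70.3%, of H3K27ac peaks 67.9% and of H3K36me3 peaks 82.0%, whereas H3K27me3 gave 44.3% and RNAPII 54.0%. Among the factors and MED1 it was 80.7% for PAX5, 74.7% for EBF1, 72.7% for MED1, 68.5% for ETS1, 64.3% for IRF4, 55.6% for TEAD1 and 33.2% for E2A. Of IKDN peaks the share was 87.1% for H3K4me3, 75.4% for H3K4me2, 67.9% for H3K4me1, 59.6% for H3K27ac, 57.9% for H3K36me3, 40.8% for H3K27me3 and 60.9% for RNAPII. For the factors and MED1 it was 69.0% for PAX5, 57.2% for EBF1, 34.8% for MED1, 47.2% for ETS1, 39.0% for IRF4, 39.1% for TEAD1 and 59.2% for E2A. The number of IKDN-only peaks per WT-only peak was 4.79 for MED1, 2.81 for IRF4, 2.67 for H3K36me3, 2.44 for ETS1, 2.20 for EBF1, 1.956 for TEAD1, 1.87 for PAX5 and 1.46 for H3K27ac. It was near 1 for H3K4me1 (1.12), H3K27me3 (1.04), H3K4me2 (1.02) and RNAPII (0.868), and lower for Aiolos (0.766), H3K4me3 (0.667) and E2A (0.343 on 11 chromosomes). With the top 50% of each list against the full other list the H3K4me3 ratio turned to 1.83, and with the incomplete chromosomes kept that of E2A was 0.939. IKDN-only peaks of EBF1 lay in IKDN-only H3K27ac for 13.8%, of E2A for 27.9%, of ETS1 for 19.4% and of IRF4 for 16.4%. WT-only peaks of the same factors lay there for 1.46, 1.58, 1.85 and 1.497%. Aiolos was the least shared, with 13.2% of 3491 WT peaks and 16.6% of 2783 IKDN peaks. Both Aiolos lists were weak, with median scores of 4.32 in WT and 4.28 in IKDN beside lowest scores of 2.99 and 2.64. Their low sharing cannot be told apart from peaks near the calling threshold. Lists of different length bias these ratios, and with equal peak numbers all factor ratios are 1 by construction while that of MED1 falls to 1.07.

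The labels give the same antibody catalogue number for several targets and different numbers for the WT and IKDN libraries of E2A, ETS1 and H3K4me3. The peak lists paired by target between genotypes: over the 5000 top-ranked peaks, the closest list of the other genotype was that of the same target for 30 of 30 paired lists. Lists of the same genotype were left out of this search, and some were closer. IKDN MED1 shared 34.5% with IKDN H3K27ac and 26.6% with WT MED1. An antibody of another specificity used in both genotypes would pair as well, so the pairing does not settle which target was bound. For E2A the Jaccard index between genotypes was 27.4%, while IKDN E2A shared 7.31% with IKDN IRF4 and 5.53% with IKDN PAX5, which carry the same catalogue number. ETS1 gave 35.5% between genotypes and 8.29% between IKDN ETS1 and WT E2A, and LHX2 shared 3.32% with IKDN ETS1 and 5.74% with WT E2A. H3K4me3 gave 73.5% between genotypes, against 1.56% between IKDN H3K4me3 and IKDN H3K4me1, which carry the same catalogue number; IKDN H3K4me3 shared 29.5% with IKDN H3K4me2 and 27.7% with IKDN H3K27ac. Aiolos gave 5.37% between genotypes, and WT Aiolos shared 13.6% with WT Ikaros. LMO2 shared 23.7% with IKDN E2A, its partner in DNA-bound LMO2 complexes.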

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

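Of the tests below, the one that set H3K4me3 peaks at stromal markers beside peaks of the same rank was planned before its result was seen; the others were chosen after the results they concern were seen.

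Peaks on unplaced or unlocalised contigs took no part in any comparison, and the 2 input libraries had no peak list to set them against. They numbered 994 over all lists; the WT PAX5 list held the largest number, 145, and the IKDN PAX5 list 141.

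The IKDN lists of H3K36me3, MED1, EBF1, PAX5, IRF4, ETS1 and TEAD1 held more than 1.5 IKDN-only peaks per WT-only peak. Deeper IKDN sequencing is argued against, since the median ratio of IKDN to WT tag totals worked out from the score steps was 0.990 (range 0.863 to 1.27), if both lists of a target use the same scale. Weak peaks near the calling threshold cannot be told apart from a wider difference: with both lists of a target held to equal length, the top 50% of IKDN peaks lacked a WT peak 1.59 times as often as the reverse, but the targets ranged from 1.17 to 3.33. IKDN immunoprecipitations that worked better at places active in both genotypes remain possible. The 6 factor or MED1 lists covered 1.55 times the share of shared distal regions in IKDN as in WT (1.12 to 2.74), with ETS1 and PAX5 counted on different chromosomes. A real difference in binding between the genotypes would look alike and stays open, untested, with 1 library each.

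H3K4me3 covered the stromal fibroblast markers less in IKDN than in WT cells, with 18 of 25 markers at 1000 bp or more in WT and 3 in IKDN. A deeper WT H3K4me3 library is argued against as the whole cause, although it held 29.6 M tags against 10.7 M in IKDN on the inferred scale, since 63.6% of the 22 WT peaks at these markers had no IKDN peak against a median of 27.3% (upper limit 40.9) for WT peaks of the same rank. Stromal cells carried along in the WT cultures cannot be told apart from a change in the B cell progenitors: by net call, RNAPII over the list lay at percentile 66.0 of random lists and H3K36me3 at 49.5, but H3K27ac at 1.60. H3K4me1 was higher in IKDN at 6 markers and lower at 2 (percentile 95.75), and H3K4me2 at 4 and 2 (percentile 70.5). The loss was thus not seen in these 2 marks. Abundant stromal genes, chosen after their values were seen, were split, with RNAPII over 36.8 kb at Col1a2 in WT and 8.49 kb in IKDN, 53.5 and 80.5 kb at Fn1, and 0 at Dcn and Lum in both, and Thy1 and Pdgfra are held by other lists as well. The H3K4me3 antibodies differ by catalogue number between the genotypes, and H3K27me3 at the same markers was higher in IKDN at 12 genes and lower at 4, which a biological loss of promoter activity would also give.

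The 3 WT-only super-enhancers in the T cell receptor alpha locus lie on copies of the same Trav13, Trav14 and Trav15 cluster. For the first and second copy, counted along the chromosome, 68.2% of 22 factor peaks had a peak of equal score (within 2%) at the matching place of the other copy, against 3.34% for random pairs of peaks, so reads shared between near-identical copies may have been counted at both. Between these and the third copy, 0 of 44 factor peaks had such a partner, which argues against reads counted in full at both. A peak of another score lay at the matching place for 11 of 22 and 10 of 22 of them. Reads shared only in part could give unequal scores, so the test cannot decide on those. The 44 also count the first and second copy apart, although these may hold the same reads. The difference between WT and IKDN was seen at all 3, and a biological one stays open, untested.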

How the results depend on the processing

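Of the alternatives described here, those restricted to autosomes, keeping incomplete chromosomes, using equal peak numbers for super-enhancers and limiting the exchange of marks to genes with both were chosen after the results were seen; the others were planned. No paired analysis was possible because each genotype and target has 1 library. Of 230 values of the main comparisons under an alternative, 137 stayed the same within the stated bounds, 75 moved, some of them to no difference between the genotypes, and 18 reversed. The integrin and focal adhesion list kept its balance under all 4 alternatives run on it, and every result that was run on autosomes alone stayed the same. Peak lists without read counts limit what depth can be judged: a region without a peak may still hold signal under the calling threshold, and the cause of a moved value was not tested unless the construction of the setting gives it.

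IKDN-only peaks per WT-only peak moved with list length, with the overlap rule and with the part of the list used. Equal numbers bring the ratio to 1 by construction for fixed-width lists (E2A, EBF1, PAX5, IRF4, ETS1 and TEAD1, each 1), and gave 1.07 for MED1, 0.990 for H3K27ac and 0.986 for H3K4me2. Reciprocal overlap of 50% gave 2.80 for MED1, 1.23 for H3K36me3, 1.03 for RNAPII and 0.975 for H3K27me3. The top 50% of each list gave 7.50 for MED1 and 0.427 for H3K4me3, and the top 50% against the full other list gave 9.83 for MED1, 5.38 for H3K36me3, 1.83 for H3K4me3 and 1.57 for H3K4me2. Keeping the incomplete chromosomes gave 0.939 for E2A and 1.19 for PAX5.

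IKDN-only per WT-only distal regions gave 0.991 with equal numbers, which the construction nearly forces, and 3.73 with MED1 in place of H3K27ac. The share of IKDN-only over the share of WT-only regions with a peak moved as follows. Equal numbers gave 0.450 for Ikaros, 2.61 for LHX2, 2.83 for LMO2, 2.85 for TEAD1, 3.79 for MED1, 2.54 for IKDN EBF1 and 0.743 for WT EBF1. Requiring H3K4me1 of the same genotype gave 0.421, 2.47, 2.65, 2.77, 3.86, 2.36 and 0.689 in the same order. H3K4me1 in place of H3K27ac gave 0.334, 3.67, 6.83, 4.19, 5.58, 2.89 and 0.677, and 0.978 for WT Aiolos. MED1 in place of H3K27ac gave 6.05 for LHX2, 6.51 for LMO2, 5.98 for TEAD1 and 4.84 for IKDN EBF1, and turned Ikaros to 2.35, WT Aiolos to 1.06 and WT EBF1 to 2.38. Most WT-only MED1 peaks (62.1%) lay outside H3K27ac. The top 50% of the factor's peaks gave 0.248 for Ikaros, 2.61 for LHX2, 2.93 for LMO2 and 3.51 for TEAD1.

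IKDN-only per WT-only super-enhancers gave 1.33 ranked by covered length, 10.9 with MED1 and 3.69 without any peak in the other genotype. Within 2.5 kb of start sites the exchange ratios were 4.10 for H3K27me3 lower with H3K27ac higher and 2.38 for the opposite. Genes with H3K27ac higher per gene lower gave 2.38 by number of peaks and 0.647 by summed score.

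Genes called higher minus lower moved in several lists, and these alternatives were not set beside random lists. A 50 kb flank gave -9 for B lineage, 1 for pre-B, 9 for junction, 0 for extra-lineage factors, -2 for myeloid, 0 for erythroid, -1 for housekeeping and 4 for factor genes. Number of peaks gave 6 for B lineage, 2 for pre-B, 2 for extra-lineage factors, 13 for cytoskeleton, 8 for growth factor, -2 for stromal, -1 for T cell, 0 for myeloid, 2 for housekeeping and 4 for factor genes. Summed score gave -18 for B lineage, -6 for pre-B, -4 for extra-lineage factors, 1 for Hippo, 1 for growth factor, -15 for cell cycle, 1 for myeloid, -3 for erythroid, -3 for housekeeping and -1 for factor genes. Equal numbers gave 1 for myeloid and 0 for housekeeping. Of 204 values of single named genes, 172 stayed the same, 30 moved and 2 reversed, both with a 50 kb flank: Acta2 dropped by 2.18 kb in IKDN and Col1a1 was 3.03 kb higher.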

Other observations

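The tests of Ikaros at genes that exchange marks and of MED1 at regions with several factors were planned before their results were seen, while the genes and the region named in these paragraphs were chosen after their values were seen.

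Outside the fixed lists, the widest gains of H3K27ac or H3K36me3 in IKDN cells included long genes with little of either mark in WT. Auts2 had no H3K27ac and no H3K36me3 in WT and 67.8 and 224 kb in IKDN cells, with 20 LHX2 peaks, while its H3K27me3 also widened, from 1.95 to 47.3 kb. Atp8a2, a phospholipid flippase, had 3.95 and 71.5 kb of H3K27ac, with H3K36me3 over 0 and 144 kb and RNAPII over 0 and 103 kb. Pde8b, a phosphodiesterase, had 1.32 and 50.6 kb of H3K27ac and 50.1 and 1.69 kb of H3K27me3. Fry had 3.40 kb of H3K36me3 in WT and 214 kb in IKDN, and Dst, a cytoskeletal linker of hemidesmosomes and microtubules, 2.74 and 160.4 kb. Cdh22, a cadherin, had H3K36me3 over 0 and 109 kb and H3K27me3 over 52.1 and 1.42 kb. Daam1, a formin of the Wnt planar cell polarity pathway, had 16.6 and 54.9 kb of H3K27ac.

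Among the widest losses, Ptprj, which codes for the receptor phosphatase CD148, had 61.3 kb of H3K27ac in WT and 16.8 kb in IKDN, and Itpr2, an inositol trisphosphate receptor, 58.3 and 27.2 kb. Dock8, an exchange factor for Cdc42 needed by lymphocytes, had H3K36me3 over 129 kb in WT and 0 in IKDN, with H3K27me3 over 29.3 and 112 kb. Arpp21, a gene of immature lymphocytes, had H3K36me3 over 83.8 kb and 0, and Arhgap15, a Rac GTPase-activating protein, 44.5 kb and 0 with RNAPII over 107 kb and 0. Sox6 had 39.3 and 6.51 kb of H3K27ac and 15.6 and 69.3 kb of H3K27me3. Rag1, a subunit of the V(D)J recombinase, had RNAPII over 22.8 and 0.625 kb and H3K27me3 over 2.44 and 9.80 kb, while Vpreb1, a surrogate light chain gene, had 14.9 and 14.8 kb of H3K27ac. The myeloid granule genes Elane and Prtn3 had RNAPII over 2.45 and 5.96 kb, and 1.48 and 6.0 kb.

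The region at Hjurp held the top-ranked peak of the IKDN H3K27ac, H3K4me1, H3K4me2 and Aiolos lists. In the WT lists of H3K27ac, H3K4me1 and H3K4me2 its best peak ranked 6187, 832 and 8528, and the WT Aiolos list had none. Of the other IKDN lists of paired targets, all but H3K27me3 had a peak there, and the best ranked 5 for EBF1, 12 for E2A, 15 for H3K36me3, 17 for PAX5, 26 for RNAPII, 89 for TEAD1, 111 for ETS1, 140 for MED1, 1343 for IRF4 and 6113 for H3K4me3. In WT the best ranked 23 for H3K36me3, 796 for PAX5, 1155 for EBF1 and 2679 for RNAPII, and the others had none. A signal that does not depend on the target was not tested. The region overlaps Mroh2a and Hjurp itself.

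A hypothesis was that genes with lower H3K27me3 and higher H3K27ac in IKDN cells were bound by Ikaros in WT cells. Of the 1089 genes, 88.7% had a WT Ikaros peak within the gene and its flanks, against a median of 81.5% (95% of draws 79.7 to 83.3) for genes with lower H3K27me3 alone, matched on window length and on WT H3K27ac. The excess of Ikaros is consistent with the hypothesis but small, and a peak within the window need not lie in the region that changed. Another hypothesis was that LHX2, LMO2 and TEAD1 together mark the IKDN-only regions that hold Mediator. MED1 lay in 69.5% of the 1056 regions with all 3 factors, against a median of 28.3% (25.7 to 31.1) for regions with 1 of them matched on width; without matching, it lay in 4.31% of regions with none, 18.8% with 1 and 39.1% with 2. That is consistent with a common set of strong IKDN enhancers, while regions with strong signal are also easier to call in every library, which was not tested.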
